A study of Homo sapiens with 3 samples.

How the data were processed

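RNA was measured in 3 libraries of 5637 cells, an established human bladder cancer line. One library came from cells given a control siRNA (siNC), and 2 came from cells given siRNA against CDCA3 (siCDCA3-1 and siCDCA3-2). Per the labels' protocols, the siRNAs were delivered with a lipid reagent, ribosomal RNA was removed from total RNA, and the libraries were read as pairs on an Illumina HiSeq instrument. The labels do not say whether siCDCA3-1 and siCDCA3-2 are different siRNA sequences or repeated cultures. The column headers name them si1 and si2, which may number siRNAs, but this is not explained. Both carry the same treatment label and were therefore treated as 1 group of 2 libraries. Nothing in the labels states that they came from separate cultures, so gene-level p-values measure the spread between these libraries. That spread exceeded counting error, with a chi-square of 401 per degree of freedom, but its source is not known and may be partly technical.

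Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36 and handled with FastQC, HISAT2 and HTSeq. A human and a mouse genome build are both listed there without a role. Because 98.6% of the accessions matched the human RefSeq gene table, the human build was taken to apply. The deposited table gave, per the file headers, a whole-number count of reads for each RefSeq transcript in each library. It also held RPKM, reads scaled by transcript length and library total, which the authors computed from the count, the transcript length and a single total per library. Recovered from the deposited values, those totals were 130459616 for siNC, 104153360 for siCDCA3-1 and 160640877 for siCDCA3-2, each larger than the sum of the library's count column. Whether counting used strand is not given in the sources used here, and the counts of overlapping or antisense genes cannot be separated.

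The table had 45006 transcripts of 19225 gene symbols. In 103 rows the symbol had been turned into a date by a spreadsheet program, and the symbol was restored from the transcript accession in all but 1 of them. Several transcripts were listed for 10131 genes, and reads had been counted for each transcript they overlapped. Where a gene had several transcripts above a minimum count, the one with the fewest had a median of 86.5% of the counts of the one with the most. Summing transcripts would therefore count reads repeatedly. The transcript with the most counts over the 3 libraries stood for each gene. The alternative was the longest transcript. Both were chosen after the data were seen. Of the accessions, 98.6% matched the RefSeq gene table of GRCh38.p14, which supplied gene coordinates on GRCh38.

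At the gene level the libraries held 50912733 counts (siNC), 40420563 (siCDCA3-1) and 62389922 (siCDCA3-2). The 10 genes with the most counts took 4.22%, 5.04% and 3.62% of them. A chi-square comparison of gene counts gave 176 per degree of freedom for siNC against siCDCA3-1, 338 for siNC against siCDCA3-2 and 401 between the siCDCA3 libraries, so no library repeated another within sampling noise. Intervals on ratios of counts are exact 95% binomial intervals and cover counting error only.

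The test had been planned on RPKM with limma, with edgeR named for the case that the table held raw counts. Because it did, edgeR 4.0.16 (R 4.3.3) was the main test: TMM scaling, a quasi-likelihood fit of siCDCA3 against siNC, a two-sided test and Benjamini-Hochberg adjustment over 10153 genes with a mean RPKM of at least 1 over the 3 libraries. The adjusted p threshold was 0.05. The common dispersion was 0.126 and the prior degrees of freedom were 12. The test reports no standard error, so those given are the absolute log2 fold change over the square root of its F statistic. The fit leaves a single residual degree of freedom, between the siCDCA3 libraries, and the lone siNC library is assumed to vary as they do. Size counts used log2(RPKM + 1), a pseudocount of 1 that understates the change of low genes, and required a difference from siNC of at least 1 in both siCDCA3 libraries. DESeq2 1.42.0 and limma 3.58.1 were alternatives. The other alternatives were pseudocounts of 0.1 and 0.5, no filter and a filter at a mean RPKM of 5, median-of-ratios scaling, quantile normalization, limma without its trend or with robust moderation, an added fold threshold of 2, and each siCDCA3 library left out.

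Before the data were examined, 26 gene lists, the main design, the alternatives other than the longest transcript and the rule for named genes were fixed. CDCA3 and MYBL2 are always named. In each direction the rule takes the 10 genes with the largest change in the less changed siCDCA3 library, among genes past the adjusted threshold with RPKM of at least 5 in siNC (lower genes) or in both siCDCA3 libraries (higher genes). Where fewer than 10 pass, the same ranking over all genes is given as values only, as happened in both directions. The values of 1 of the 10 higher genes are not reported here. Each list adds its members past the threshold, up to 4, or else its 2 members with the highest mean RPKM. Genes named outside that rule are said to have been chosen after their values were seen. The lists were tested with camera (in limma) on log2(RPKM + 1) with a preset correlation of 0.01, with adjustment over the 22 lists that had at least 3 measured members. With the preset correlation, camera compares genes with genes, so its p-value does not measure spread between cultures. An estimated correlation and the fry rotation test were alternatives. Both rest on the single residual degree of freedom, so few lists could pass them after adjustment. Each list's median difference was also placed, per library, among 10000 random lists of the same size matched on mean RPKM and, where stated, also on length and GC content. The lists of mitochondrially encoded mRNAs and of abundant noncoding RNAs were not analysed here.

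The edgeR procedure was tested on simulated data for siCDCA3 against siNC, with 50 of 10153 genes changed at each fold size. It recovered 26% of genes changed 4-fold, 90% of those changed 8-fold and 100% of those changed 16-fold or 32-fold, with 10 false calls. DESeq2 recovered 44%, 90%, 98% and 100%, with 32 false calls. Every simulated library was drawn with edgeR's trended dispersion. Values in the Results show that this setting does not describe the real libraries, so these rates and false calls may not hold for them. In a simulated test of the lists, camera ranked the 1 shifted list first and called no other of the 22. Genes were drawn independently there, so it could not show false calls that come from correlated genes. In the real data the estimated correlation was 0.75 for heat shock genes and 1 for ribosome biogenesis, but such estimates rest on the single residual degree of freedom. Because both siCDCA3 libraries are set against the same siNC library, 100 simulations of unchanged groups with edgeR's trended dispersion gave the values that arise with no effect. After the data were seen, these were repeated with the dispersion multiplied by 0.827, which meets the observed variance between the siCDCA3 libraries. Python with numpy, pandas, scipy and matplotlib served for the joins, resampling and plots.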

Results

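The data are RNA read counts and RPKM values from 5637 bladder cancer cells: 1 library after a control siRNA (siNC) and 2 libraries after siRNA against CDCA3 (siCDCA3-1 and siCDCA3-2). CDCA3 encodes a cell division cycle associated protein that takes part in entry into mitosis. The series was designed to find genes downstream of CDCA3. The libraries held 50912733, 40420563 and 62389922 gene-level counts in that order, and 10153 genes had a mean RPKM of at least 1. Since siNC has no replicate, values are given per library, and adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another tool is named. In those tests the lone siNC library is assumed to vary like the siCDCA3 libraries. Values given below go against that assumption.

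The targeted gene was low in both siCDCA3 libraries. CDCA3 (NM_031299.6, GRCh38 chromosome 12, 6844798 to 6851286) had an RPKM of 5.52 in siNC, 0.574 in siCDCA3-1 and 1.40 in siCDCA3-2. Its RPKM was 10.4% of the siNC level in siCDCA3-1 (95% counting interval 8.45% to 12.6%) and 25.3% in siCDCA3-2 (22.6% to 28.3%), from 1303, 108 and 406 counts. The log2 fold change was -2.50 with a standard error of 0.67 and an unadjusted p of 0.00246 in edgeR. After adjustment over all genes this difference did not pass (edgeR adjusted p = 0.9997). MYBL2, a transcription factor of proliferating cells, had RPKM of 76.6 in siNC, 51.6 in siCDCA3-1 and 75.9 in siCDCA3-2 (edgeR adjusted p = 0.9997).

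The comparison of siCDCA3 with siNC asks which transcripts differ once CDCA3 is depleted. ASNS, the enzyme that makes asparagine, fell from an RPKM of 40.5 in siNC to 1.02 in siCDCA3-1 and 1.40 in siCDCA3-2. CHAC1, which degrades glutathione, fell from 15.7 to 1.04 and 0.434. NUPR1, a small stress-induced nuclear protein, fell from 3.74 to 0.0211 and 0.0478 and was chosen after its values were seen, because its siNC level lay under the minimum of the naming rule. These 3 genes were the only ones past the edgeR threshold, and 0 genes rose past it.

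The log2 fold change of ASNS (NM_183356.3, GRCh38 chromosome 7, 97851677 to 97928441) was -5.06 with a standard error of 0.50 (edgeR adjusted p = 0.001428). Its RPKM was 2.51% of the siNC level in siCDCA3-1 (2.21% to 2.85%) and 3.45% in siCDCA3-2 (3.16% to 3.77%). For CHAC1 (NM_024111.4, GRCh38 chromosome 15, 40953471 to 40956512) the log2 fold change was -4.38 with a standard error of 0.63 (edgeR adjusted p = 0.03585). NUPR1 (NM_001042483.1, GRCh38 chromosome 16, 28532708 to 28538974) had 445 counts in siNC against 2 and 7 in the siCDCA3 libraries. The ratios were 0.563% (0.068% to 2.05%) and 1.28% (0.511% to 2.65%) of the siNC level, with an edgeR adjusted p of 0.01843. All 3 calls were lost under limma on log2(RPKM + 1) as deposited, whose adjusted p was 0.1462 for ASNS, 0.4581 for CHAC1 and 0.9649 for NUPR1, while limma after quantile normalization kept the ASNS call (adjusted p = 0.009549). At a mean RPKM of at least 5, a filter that removes NUPR1, the edgeR adjusted p was 0.1032 for ASNS and 0.7714 for CHAC1. In edgeR 134 genes had an unadjusted p under 0.05 (36 higher and 98 lower), fewer than the 508 expected by chance. The test thus gave too few low p-values, and a high adjusted p does not show that a gene was unchanged. DESeq2 called 2 higher and 8 lower genes, and limma called none, with 121 genes at an unadjusted p under 0.05.

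Among genes with a siNC RPKM of at least 5, the other 8 of the 10 with the strongest decrease in both libraries did not pass the threshold of the filtered edgeR test. They are given as values. CBS, an enzyme of cysteine synthesis, had RPKM of 23.3 in siNC, 3.35 in siCDCA3-1 and 1.79 in siCDCA3-2. It may share reads with the near-identical gene CBSL, which was not measured, so its level is uncertain. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, had 34.1, 5.50 and 4.59, and TRIB3, a pseudokinase of the stress response, had 31.3, 3.17 and 5.28. For PSAT1, an enzyme of serine synthesis, RPKM was 38.4, 3.09 and 9.44. The tRNA synthetases CARS and MARS had 36.1, 8.59 and 7.73, and 60.1, 13.9 and 16.2. DDIT3, which encodes the stress transcription factor CHOP, had 10.7, 2.43 and 1.52, and the glycine transporter SLC6A9 had 8.97, 2.07 and 0.575. The edgeR log2 fold changes of these 8 genes ran from -3.15 for CBS to -1.99 for MARS, with adjusted p from 0.09095 for CBS and TRIB3 up to 0.9997. Without the filter on low values edgeR called 6 of the 8, with adjusted p of 3.6e-06 for CBS, 3.4e-05 for TRIB3, 0.0001892 for PCK2, 0.0003809 for PSAT1, 0.001094 for SLC6A9 and 0.02799 for CARS. DESeq2 called CBS, PCK2, TRIB3 and CARS lower, with DESeq2 adjusted p of 0.0004499, 0.0004934, 0.0004499 and 0.04805. DESeq2 also called NCF1 lower (RPKM 3.12, 0.270 and 0.239, with a DESeq2 adjusted p of 0.04805), a gene that may share reads with its pseudogenes and was chosen after its values were seen.

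**Figure D1:**
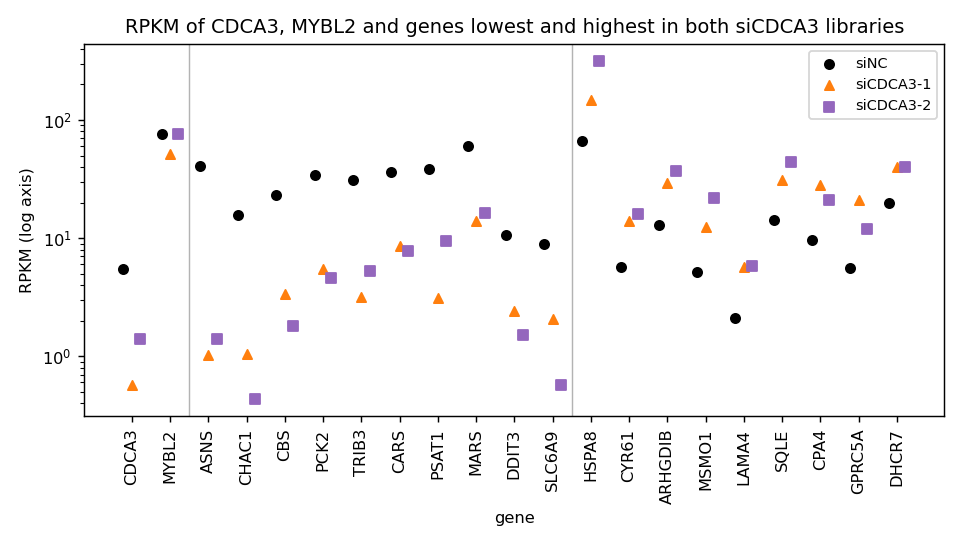
RPKM on a log axis in siNC (circles), siCDCA3-1 (triangles) and siCDCA3-2 (squares), with each point 1 library. Shown are CDCA3 and MYBL2, then the 10 lower genes and 9 of the 10 higher genes of the naming rule. ASNS dropped from 40.5 to 1.02 and 1.40, while HSPA8 was at 65.9, 148 and 316.

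Genes with an RPKM of at least 5 in both siCDCA3 libraries were ranked by their increase. Among the 10 with the largest increase in both libraries were MSMO1, SQLE and DHCR7, which encode enzymes of cholesterol synthesis. None of the 10 passed the edgeR test, so values only are given, for 9 of them. MSMO1 had RPKM of 5.20 in siNC, 12.5 in siCDCA3-1 and 21.8 in siCDCA3-2. SQLE had 14.2, 31.2 and 44.1, and DHCR7 had 19.8, 39.96 and 39.91. HSPA8, a constitutive chaperone, had 65.9, 148 and 316. CYR61, a matrix-associated signalling protein, had 5.72, 13.9 and 15.95, and ARHGDIB had 12.8, 29.5 and 36.9. The others were LAMA4 (2.11, 5.73 and 5.84), CPA4 (9.70, 28.3 and 20.9) and GPRC5A (5.54, 20.9 and 11.99). The edgeR log2 fold changes of these 9 genes ran from 1.02 for DHCR7 to 1.80 for HSPA8, each with an adjusted p of 0.9997. DESeq2 called 2 genes higher, both under an RPKM of 5 in siCDCA3-1 and chosen after their values were seen. They were DKK1, a secreted Wnt inhibitor, with RPKM of 0.667, 3.53 and 13.8 (DESeq2 adjusted p = 0.001622), and PCDH7, with 0.328, 1.47 and 2.28 (DESeq2 adjusted p = 0.02575). Without the filter edgeR also called DKK1 (adjusted p = 0.001094) and did not call PCDH7 (adjusted p = 0.1128).

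By size alone, 10 genes were at least 2-fold higher and 73 at least 2-fold lower than siNC in both siCDCA3 libraries. These 10 are not the same set as the 10 higher genes of the naming rule. Of the latter, DHCR7 (0.973) and GPRC5A (0.991) had a log2 difference under 1 in siCDCA3-2. The siCDCA3 libraries differed 2-fold from each other at 876 genes. In siCDCA3-1 by itself 86 genes were higher and 177 lower, and in siCDCA3-2 by itself 144 were higher and 332 lower. Setting siCDCA3-1 against the other 2 libraries in the same way gave 127 genes and setting siCDCA3-2 against the others gave 255, compared with 83 for siNC. Unchanged groups simulated with edgeR's trended dispersion gave means of 222.1 higher and 149.3 lower genes, but these simulated libraries lay farther apart than the real siCDCA3 libraries (1326 genes 2-fold apart against 876), which inflates both counts. With the dispersion scaled so that the variance between the siCDCA3 libraries was met, a setting added after the data were seen, the means were 148 higher (119 to 181) and 95.1 lower (67 to 125) genes, with 982 genes 2-fold apart. That simulation also fails to describe these libraries, since it gave means of 489.5 higher and 492.2 lower genes in siCDCA3-1 alone and 494.4 and 489.1 in siCDCA3-2 alone, far more than observed, and a range of 910 to 1048 genes 2-fold apart. Neither simulation therefore gives a calibrated chance count for the 10 and 73 genes.

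The differences from siNC in the siCDCA3 libraries had a Pearson correlation of 0.153 and a Spearman correlation of 0.083 across the 10153 genes, which are not independent replicates. Simulated unchanged groups that share the siNC library gave a Pearson correlation of 0.501 on average, and 0.4995 with the scaled dispersion. The observed covariance was 0.0316 and the simulated ones 0.221 and 0.181. The low observed value goes against the assumption that siNC varies like the siCDCA3 libraries. Part of the observed correlation may come from the shared siNC library, which could not be split. Over log2(RPKM + 1), siNC correlated at 0.963 with siCDCA3-1 and at 0.939 with siCDCA3-2, and the siCDCA3 libraries correlated at 0.915 with each other.

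**Figure D2:**
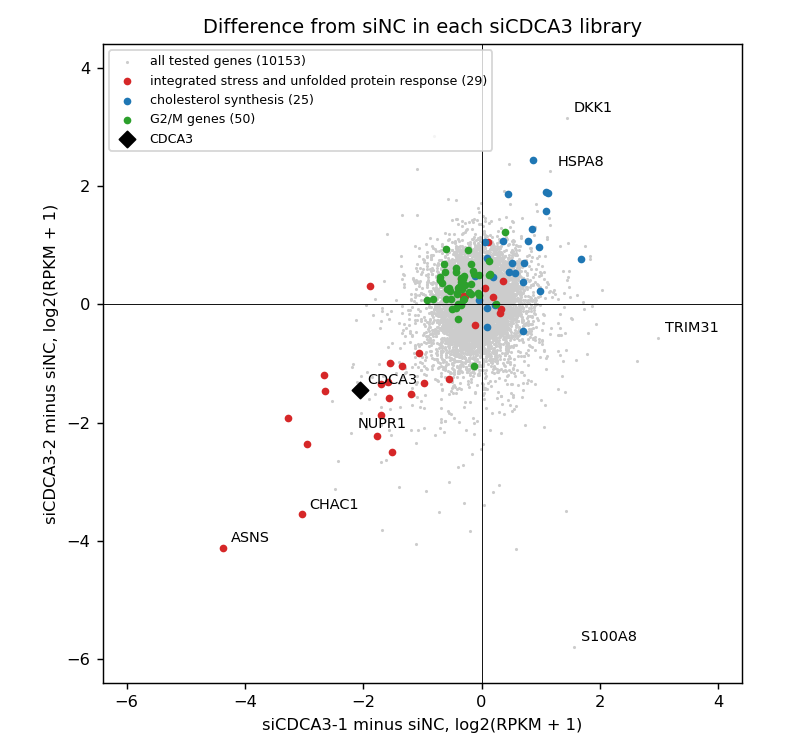
Difference from siNC in log2(RPKM + 1) in siCDCA3-1 (horizontal) and siCDCA3-2 (vertical) for 10153 genes (grey), with the integrated stress list (red), cholesterol synthesis (blue), G2/M genes (green) and CDCA3 (black diamond). Most stress genes lie toward the lower left, most cholesterol genes toward the upper right, and most G2/M genes left of and above the origin.

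Genes of the integrated stress and unfolded protein response fell as a list. Of 29 measured members, 19 were lower and 4 higher in both siCDCA3 libraries, with median log2 differences of -1.34 in siCDCA3-1 and -1.19 in siCDCA3-2. ASNS and CHAC1 passed the edgeR test over all genes, and 13 members passed when adjusted over the list alone, all lower. Besides genes named above, these included PHGDH, the first enzyme of serine synthesis (RPKM 154, 47.0 and 41.3), SHMT2, which makes glycine from serine in mitochondria (69.4, 10.2 and 24.5), and SESN2 (14.1, 4.11 and 4.02), all chosen after their values were seen. The chaperone genes HSPA5 (106, 134 and 101) and PDIA4 (53.1, 61.0 and 57.9), also chosen after their values were seen, were not lower in both libraries. The 11 ER chaperone members, a set written after their values were seen, did not fall as a set. Their medians were 0.057 in siCDCA3-1, where 5 were lower, and 0.133 in siCDCA3-2, where 4 were lower. The camera test with the preset correlation gave an adjusted p of 4.9e-29. Here and in the lists below, that p-value compares genes with genes and does not measure spread between cultures. With an estimated correlation the call was lost (adjusted p = 0.4831), although that estimate, -0.005, lay under the preset 0.01. That setting and its estimate rest on the single residual degree of freedom, so the estimate cannot show how correlated the members are. In each siCDCA3 library the median lay at percentile 0.00 of 10000 random lists matched on expression. Here and below, those lists hold genes drawn independently, so members that move together for any reason can give an extreme percentile. For this list and those below, both libraries are set against the same siNC library, so their agreement is not 2 independent results.

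NF-kB inflammatory genes also fell as a list, with 19 of 24 measured members lower in both siCDCA3 libraries and 0 higher in both. The medians were -0.757 and -1.09, at percentile 0.00 of the matched random lists in each library. No member passed the edgeR test, whether adjusted over all genes or adjusted over the list alone. NFKBIA, the feedback inhibitor, had RPKM of 104, 70.1 and 47.2, and TNFAIP2 had 135, 137 and 25.3. Secreted members chosen after their values were seen were IL1A (65.6, 13.6 and 31.0), CXCL8 (92.7, 33.4 and 40.7) and CSF3 (31.6, 7.07 and 11.54). The camera adjusted p was 2.2e-24 with the preset correlation, and the call was lost with an estimated correlation (adjusted p = 0.4831).

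Cholesterol synthesis genes rose as a list. Of 25 measured members 19 were higher in both siCDCA3 libraries and 0 lower in both, with medians of 0.571 and 0.698, above all matched random lists in each library. The shared siNC library could move both medians together. The list held MSMO1, SQLE and DHCR7, and FDFT1 had RPKM of 42.2, 70.0 and 69.1 while FDPS had 78.3, 83.0 and 74.5. No member passed the edgeR test over all genes or adjusted over the list alone. The camera adjusted p was 4.4e-17, and it was 0.4831 with an estimated correlation.

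Basal and squamous genes fell as a list, with medians of -0.452 and -0.295 and 10 of 16 measured members lower and 0 higher in both libraries. KRT5 had RPKM of 421, 218 and 200 and KRT17 had 429, 210 and 138. The camera adjusted p was 6.0e-08, and it was 0.5658 with an estimated correlation. The glycolysis and hypoxia list had medians of 0.256 and 0.316 (camera adjusted p = 0.007715, and adjusted p = 0.8545 with an estimated correlation). Its members were mixed: of 26, 14 were higher in both libraries, 5 were lower in both and 7 went opposite ways. The glycolysis call was also lost at a mean RPKM of at least 5 (adjusted p = 0.239). GAPDH had RPKM of 654, 636 and 533 and ENO1 had 392, 304 and 596. No member of the basal or the glycolysis list passed the edgeR test over all genes or adjusted over the list alone.

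The remaining 2 lists that camera called higher had medians of opposite sign in the siCDCA3 libraries. Heat shock genes had medians of -0.120 in siCDCA3-1 and 0.760 in siCDCA3-2 (camera adjusted p = 0.003194, and adjusted p = 0.9747 with an estimated correlation). HSPA8 was higher in both libraries, whereas HSP90AA1 had RPKM of 200, 183 and 413. Ribosome biogenesis genes had medians of -0.251 and 0.830 and 22 of 24 members went opposite ways (camera adjusted p = 0.003194, and adjusted p = 0.9747 with an estimated correlation). Without a filter on low values both calls were lost (camera adjusted p = 0.05274 for heat shock genes and 0.08865 for ribosome biogenesis). NPM1 had RPKM of 229, 184 and 371 and FBL had 97.0, 93.7 and 114.

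Camera called no cell cycle list in the main setting. The G2/M, G1/S, MuvB and CDCA lists each had medians of opposite sign in the siCDCA3 libraries. G2/M genes, the class that CDCA3 itself belongs to, had medians of -0.349 in siCDCA3-1 and 0.290 in siCDCA3-2, and 39 of 50 members went opposite ways (camera adjusted p = 0.9085). Against matched random lists the G2/M median lay at percentile 0.00 in siCDCA3-1, where 45 members were lower, and at 99.98 in siCDCA3-2. With lists also matched on length and GC content, the siCDCA3-2 value was 97.21. UBE2C had RPKM of 69.6, 43.4 and 89.8, and CDC25B had 67.1, 61.5 and 31.9. G1/S genes had medians of -0.144 and 0.166 over 41 members (camera adjusted p = 0.6855), among them PCNA with RPKM of 72.6, 71.6 and 66.9 and MCM7 with 63.96, 63.4 and 59.6. The MuvB complex and partners (medians -0.165 and 0.074, adjusted p = 0.9085) and the CDCA family and mitotic entry genes (medians -0.122 and 0.273, adjusted p = 0.6855) were not called by camera either. CDCA4 had RPKM of 24.5, 18.99 and 23.1, and TFDP1, a partner of MuvB, had 47.4, 24.6 and 74.7. Of the replication-dependent histones 9 of 55 were measured, with medians of 0.654 and 0.042 (camera adjusted p = 0.2003, and from 0.0235 without a filter to 0.9912 with fry over the alternatives). HIST1H1C had RPKM of 10.5, 17.98 and 5.24, and HIST1H2BK had 7.94, 20.2 and 9.02. Over the mean of the siCDCA3 libraries, the median, the mean and the camera direction differed in sign in 8 lists, none of them called.

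**Figure D3:**
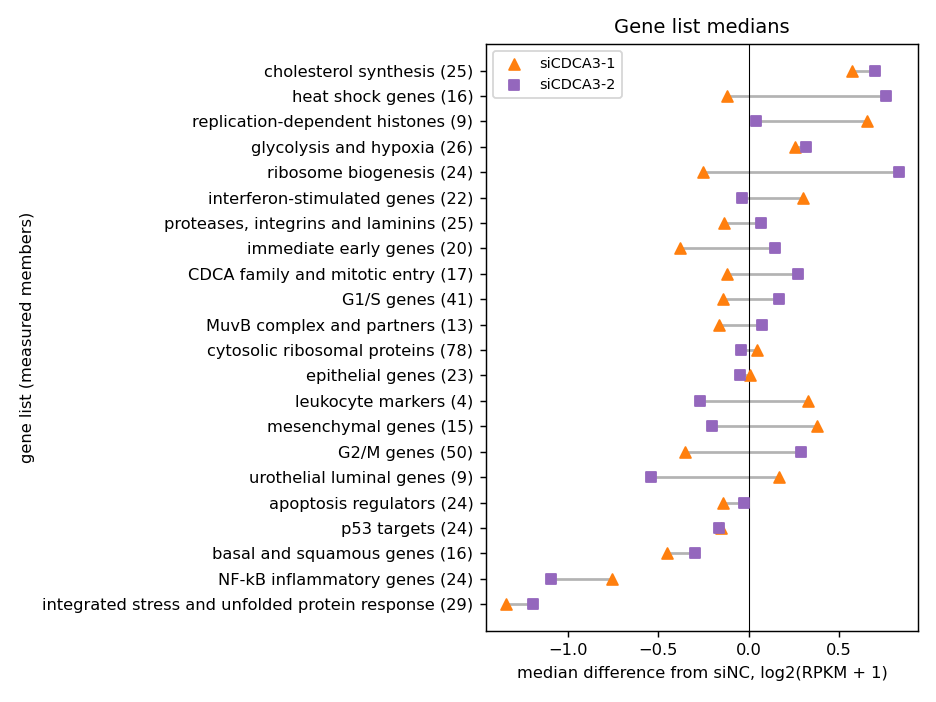
Median over measured members of the difference from siNC in log2(RPKM + 1) for each tested list, in siCDCA3-1 (triangles) and siCDCA3-2 (squares), with the number of members in parentheses. The integrated stress list sits at -1.34 and -1.19, cholesterol synthesis at 0.571 and 0.698, and ribosome biogenesis at -0.251 and 0.830.

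Lists that camera did not call also reached extreme percentiles in single libraries. In siCDCA3-1 immediate early genes lay at 0.00, and mesenchymal genes, histones, interferon-stimulated genes, cytosolic ribosomal protein genes and leukocyte markers at 100, 100, 99.99, 99.54 and 98.8. In siCDCA3-2 urothelial luminal genes lay at 0.30 and p53 targets at 2.36. Cytosolic ribosomal protein genes lay at 26.05 in siCDCA3-2, and at 0.86 with lists also matched on length and GC content.

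Among lists for cell death and signalling, p53 targets had medians of -0.153 and -0.162 over 24 members (camera adjusted p = 0.0513, and 0.02326 with median-of-ratios scaling, the lowest of the alternatives, up to 0.8545 with an estimated correlation), with SESN2 the single member that passed when adjusted over the list alone. CDKN1A had RPKM of 49.6, 42.5 and 53.2, and BAX had 29.5, 28.3 and 31.4. Apoptosis regulators had medians of -0.144 and -0.026 (adjusted p = 0.2789), with BCL2L1 at 32.1, 48.2 and 23.5 and MCL1 at 29.2, 27.2 and 33.2. Interferon-stimulated genes had medians of 0.299 and -0.038 (adjusted p = 0.09273), with ISG15 at 43.5, 40.3 and 42.8 and UBE2L6 at 16.4, 20.95 and 2.85. Immediate early genes had medians of -0.380 and 0.144 (adjusted p = 0.7153), with JUNB at 105, 73.1 and 55.8 and IER2 at 42.02, 49.4 and 41.1.

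Of the lists for cell identity and adhesion, camera called the basal and squamous list and did not call the next 4. Mesenchymal genes had medians of 0.380 and -0.200 (adjusted p = 0.6855), with FN1 at an RPKM of 60.8, 158 and 25.8 and TGFBI at 44.3, 60.4 and 26.1. Epithelial genes had medians of 0.007 and -0.049 (adjusted p = 0.9636), with KRT19 at 972, 822 and 643 and KRT7 at 341, 356 and 377. Urothelial luminal genes had medians of 0.168 and -0.540 (adjusted p = 0.2861), with KLF5 at 55.5, 53.4 and 41.98 and ELF3 at 14.97, 54.0 and 7.89. Proteases, integrins and laminins had medians of -0.134 and 0.067 (adjusted p = 0.6855), with ITGB4 at 144, 103 and 113 and ITGA3 at 108, 92.5 and 107. Cytosolic ribosomal protein genes had medians of 0.045 and -0.042 over 78 members (adjusted p = 0.9085), with RPL8 at 905, 869 and 797 and RPLP1 at 1071, 1048 and 762.

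Few markers of other cell types were measured. Of 19 leukocyte markers 4 were, with medians of 0.329 and -0.266 (camera adjusted p = 0.9085), and LAPTM5 had RPKM of 22.3, 11.7 and 18.6 and CORO1A had 12.01, 15.9 and 8.75. Of 11 fibroblast markers 2 were measured, COL1A1 (6.96, 8.33 and 2.26) and THY1 (3.39, 3.81 and 3.42). EGFL7 (2.68, 1.85 and 1.21) was the 1 measured of 11 endothelial markers.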

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

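The longest-transcript setting was chosen after the data were seen. Depth limits the precision of the NUPR1 ratio, which rests on 2 and 7 counts in the siCDCA3 libraries. All 26 genes followed across the tests kept the sign of their fold change under each test that included them, and the correlation of the siCDCA3 differences stayed between 0.141 and 0.169. CDCA3 kept its direction and stayed short of the threshold under all tests, with adjusted p from 0.0604 (no filter) to 1, and its log2 fold change was -3.19 and -2.04 with a single siCDCA3 library. The filter at a mean RPKM of 5 removes CDCA3. No paired analysis was possible because siNC has 1 library, so the groups share fewer than 2 replicate numbers. Leaving out a siCDCA3 library leaves 1 against 1 with no residual degrees of freedom, so gene and list calls have no value there.

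The count of genes called higher was 0 in edgeR, 4 without a filter and 2 with DESeq2. The count called lower was 3 in edgeR. It was 18 without a filter and 8 with DESeq2, both including the same 3 genes, and 1 with limma after quantile normalization. It was 0 with limma at pseudocounts of 1, 0.1 and 0.5, with limma without the trend or with robust moderation, and in edgeR at a mean RPKM of at least 5. ASNS passed in 5 of 11 alternatives (adjusted p 3.4e-17 to 0.2107), CHAC1 in 4 of 11 (4.2e-10 to 0.9999) and NUPR1 in 4 of 10 (1.5e-08 to 1). Genes 2-fold higher in both libraries went from 10 to 32 with a pseudocount of 0.1, and genes 2-fold apart between the siCDCA3 libraries went from 876 to 1512 with that pseudocount and to 563 at a mean RPKM of at least 5, which tests fewer genes. With a single siCDCA3 library, 86 to 144 genes were 2-fold higher and 177 to 332 lower. Camera called 7 lists, against 0 with an estimated correlation and 0 with fry, which both rest on the single residual degree of freedom. The estimated correlation lay under the preset 0.01 in the integrated stress (-0.005), NF-kB (-0.014), cholesterol (0) and basal (-0.067) lists. The estimate was 0.015 for glycolysis, 0.75 for heat shock genes and 1 for ribosome biogenesis. These estimates come from the single difference between the siCDCA3 libraries. They therefore cannot show whether correlation between members explains the losses. Of the 7, the integrated stress, NF-kB, cholesterol and basal lists kept the call in 8 of 10 settings. Without a filter the heat shock and ribosome biogenesis calls were lost, and at a mean RPKM of at least 5 the glycolysis call was lost. Without a filter, p53 targets and histones were called as well, and p53 targets also with median-of-ratios scaling, quantile normalization or the longest transcript. Without siCDCA3-2 the medians of heat shock genes (-0.120) and ribosome biogenesis (-0.251) reversed. Without siCDCA3-1 they were 0.760 and 0.830. For the other changes the cause was not tested.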

Other observations

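The tests below were chosen after the result was seen, except those of genomic DNA and of length or GC content between the siCDCA3 libraries. A number of genes set the siCDCA3 libraries apart from each other, and all are given as values chosen after they were seen. The inflammation-associated genes S100A8, S100A9 and LCN2 were low in siCDCA3-2: S100A8 had RPKM of 150 in siNC, 445 in siCDCA3-1 and 1.73 in siCDCA3-2, S100A9 had 2601, 2959 and 286, and LCN2 had 1429, 1170 and 138. IGFBP3, which binds insulin-like growth factors, had 153, 228 and 7.69. In the same library the cyclin gene CCND1 (6.12, 2.34 and 33.6) and the collagenase gene MMP1 (7.64, 3.96 and 60.9) were high. TRIM31 (0.540, 11.2 and 0.0427) and LGALS9 (1.91, 17.03 and 0.498) were high in siCDCA3-1. Several genes lay on opposite sides of siNC in the siCDCA3 libraries, with the mitotic kinase gene CDK1 at 11.9, 7.55 and 23.8, MYC at 27.5, 17.3 and 54.9, SRM at 23.7, 21.1 and 65.4 and HSPD1 at 53.3, 49.1 and 123.

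The integrated stress list was low in both siCDCA3 libraries. The tables argue against scaling between libraries, since the list median stayed at -1.17 after median-of-ratios scaling, and against length or GC content, since it was -1.10 after trends with expression, length and GC were removed. A loss of ATF4-type signalling rather than of the ER chaperone program stays an untested hypothesis. Its sets were written after their members' values were seen, so the medians are description only: -1.68 over 18 ATF4 and stress members and 0.084 over 11 ER chaperone members (difference -1.76), and -0.832 over 20 cytosolic tRNA synthetases, including CARS and MARS, and 0.116 over 17 mitochondrial ones (difference -0.948). Whether the siNC culture was itself under amino acid stress cannot be told apart from an effect of the siRNA, because there is 1 siNC library: the siCDCA3 libraries differ from each other by a median of 0.229 on this list, and no other siNC culture shows where its level usually lies.

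The siCDCA3-2 library had few genes at 0 counts: 710, against 2388 in siNC and 2545 in siCDCA3-1. Depth is argued against, since thinned to the total of siCDCA3-1 it still had a mean of 1094.4 genes at 0, against 2679.3 in thinned siNC. RNA from another tissue stays open: 9 transcripts abundant in liver, blood, pancreas, lung, lens, testis or brain together had an RPKM of 0.0199 in siCDCA3-2 (36 counts, 95% Poisson interval 0.014 to 0.0276), which spans the 0.0208 of 374 olfactory receptor genes, against 0.00818 in siNC and 0.0137 in siCDCA3-1. A candidate explanation is a trace of genomic DNA: taste receptor, vomeronasal receptor, keratin-associated protein and defensin genes together had an RPKM of 0.0265, 3.06 times the higher of the other libraries, with a weaker contrast to siCDCA3-1 in defensins (0.0105 against 0.00806, from 28 and 14 counts) and vomeronasal receptors (0.0436 against 0.0277, from 34 and 14 counts) than in taste receptors (0.0349 against 0.0112) and keratin-associated proteins (0.0248 against 0.00618). These levels are far below the minimum mean RPKM of 1 for tested genes, and no biological explanation was tested.

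The siCDCA3 libraries differed more from each other than either did from siNC. Length or GC content is argued against as the main source, since with expression they explained 15.9% of the variance of the difference between the siCDCA3 libraries, and 658 of the 9960 genes with a GC value were still 2-fold apart. Different siRNA sequences or culture states stay open and cannot be told apart, since the labels do not say which the numbers mark and no pair from the same siRNA and day is at hand. The correlation between the siCDCA3 libraries was 0.9154.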
